A study of Mus musculus with 2 samples.

How the data were processed

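Hearts of male B6CASTF1/J mice aged 2 months were profiled with long-read RNA sequencing, an assay in which each read is meant to cover a transcript from end to end. B6CASTF1/J mice are first-generation hybrids of a C57BL laboratory strain and CAST, a strain derived from wild mice. The series held 1 group of 2 libraries, each made from 2 µg of RNA, per the labels. The labels gave the libraries separate biosamples from numbered animals, but another text field gave both libraries the number of the same animal. The libraries were treated as separate samples because of the biosample labels, and all differences between them measure the spread between these 2 libraries. They were named replicate 1 and replicate 2 after the replicate numbers in the labels.

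The deposited tables held counts of reads per transcript model, 1 table per library, with no normalization and no pooling of replicates. The deposited values were whole numbers of at least 1. Reads had been aligned to the mouse genome build mm10 and compared with the GENCODE M21 annotation, per the text files deposited beside the tables. The deposited annotation files named TALON, a program that assigns long reads to transcript models, as the source of the models that GENCODE M21 lacks. The aligner, the read correction and all program versions were not given in the sources used here. Exon numbers and model lengths, per the file headers, are properties of a model and not of single reads, so the length of a known transcript is its annotated length. The reference annotation used here was the same release: all 17830 known transcripts that were read had an entry there, and all 17830 had the same length.

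Each model carried a class in the deposited tables. Known transcripts match GENCODE M21. An incomplete splice match (ISM) holds a consecutive part of the introns of a known transcript, or part of a single exon. NIC models combine known splice sites in a way the annotation does not list, and NNC models have at least 1 splice site the annotation lacks. Genomic models overlap a gene without following its splice sites. Antisense and intergenic models lie in loci opposite to or outside annotated genes. How strand was assigned to reads was not given in the sources used here, so levels of antisense loci and of overlapping genes are uncertain. Reads of near-identical copies, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or a gene and its processed pseudogene, were used as the authors had assigned them, and their split is uncertain.

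Reads of all classes were summed per annotated gene. Levels in CPM, the reads of a gene scaled to a common library total, were calculated from the deposited counts with the total of annotated nuclear genes as the denominator, 430251 reads in replicate 1 and 629896 reads in replicate 2, so spike-in RNAs and mitochondrial genes did not enter it. A count of 0 allows up to 3 reads, which is 6.97 CPM in replicate 1 and 4.76 CPM in replicate 2. Means are given with the SD over the 2 libraries. Shares in a single library have exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, because reads copied from the same molecule cannot be told apart here.

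A series with 1 group has no contrast for a replicated test. The 2 libraries were compared gene by gene with an exact two-sided binomial test on the raw reads, given their sum and the nuclear totals, with Benjamini-Hochberg adjustment over the 8098 genes with at least 10 summed reads. A gene passed the test at an adjusted p under 0.05 and was called where it also differed at least 2-fold. The test compares 2 libraries and covers counting error only, so its p-values say nothing about mice in general. Log2 ratios are replicate 1 over replicate 2 and were calculated with 0.5 reads added to each count. Agreement was measured by Pearson's r of log2(CPM + 1) and by Spearman's rho across genes, which are not independent replicates. The coefficient of variation beyond counting error was calculated over genes with at least 100 summed reads, with an interval from 500 bootstrap resamples of the genes.

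Gene lists were fixed before the data were examined, as were the tests, thresholds, isogene pairs and genes for isoform use. There were 22 lists with 287 genes, and 26 isogene pairs. For each list with at least 3 members of 10 or more summed reads, the median log2 ratio was set against 10000 random lists of the same size, matched on expression level. Isoform use was compared over known transcripts with at least 10 summed reads in genes with at least 20 reads in each library, by Fisher's exact test or, with more than 2 transcripts, by a chi-square permutation test with 100000 random tables. A gene was called at an adjusted p under 0.05 and a share change of at least 10 percentage points. Spliced models were matched between libraries by chromosome, strand and intron chain. Genes were named by a fixed rule: the 20 highest mean CPM values, the 3 highest members of each list and its most different member past the test, the 10 largest differences in each direction among called genes, all isogene pairs with at least 50 reads, the 15 lowest main isoform shares among fixed genes with at least 50 known-transcript reads in each library, and the 10 most read shared NIC or NNC models. Ttn and Ryr2 were named in advance as long genes. Other genes outside the rule are marked as chosen after their values were seen. A few genes that the rule takes are not reported here.

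Alternatives were other scalings (TMM in edgeR 4.0.16 and median-of-ratios size factors in DESeq2 1.42.0, both in R 4.3.3), other read minimums and pseudocounts, known transcripts alone, models of the genomic class left out, no fold minimum, looser matching of junctions, and each replicate alone. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The library test, the coefficient of variation, the isoform test and the percentiles of lists were tested on simulated data drawn from the means and totals of these libraries; the other steps were not. The library test recovered 93.6% of 94 genes changed 2.83-fold and 99.1% of 106 genes changed 4-fold with at least 50 reads, and called 8 of 7846 unchanged genes. With a simulated coefficient of variation of 0 and 7% over 1747 genes, the estimates were 0 and 7.06%. The isoform test recovered 97% of 200 genes with a simulated change of 30 percentage points, and called 4 of 323 unchanged genes. Of 40 simulated random lists, 5% fell outside the central 95% of random medians.

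The labels named SIRV and ERCC spike-in RNAs, which are synthetic transcripts of known sequence added to the sample. The tables used here gave reads for 43 ERCC transcripts and for 0 SIRV transcripts, so SIRV RNAs were not analysed here. Splice-site sequences and runs of adenine next to transcript ends were not examined, because no genome sequence was used here. Parental alleles were not separated.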

Results

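The hearts of 2-month-old male B6CASTF1/J mice were profiled in 2 long-read RNA libraries of a single group. Replicate 1 held 454069 reads over 56790 transcript models and replicate 2 held 661958 reads over 69026 models. Mouse models took 447689 and 654198 of these reads, and ERCC spike-in RNAs took the rest, 1.41% (95% interval 1.37 to 1.44) and 1.17% (1.15 to 1.20). Annotated genes received 96.7% of mouse reads in replicate 1 and 97.0% in replicate 2. At least 1 read was found for 12700 genes in replicate 1 and 13326 genes in replicate 2. The design holds no treatment or second tissue, so the data describe the adult heart and compare its 2 replicates. Values are mean ± SD with n = 2 libraries unless a single library is named.

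The transcripts most read in these hearts encoded the contractile apparatus and the mitochondrial machinery that fuels it. Myh6, the alpha myosin heavy chain of the adult mouse heart (ENSMUSG00000040752.16, mm10 chr14:54941921-54966927, minus strand), stood first at 32071 ± 6249.5 CPM. Slc25a4, the heart form of the mitochondrial ADP/ATP carrier, reached 20797 ± 1626 CPM and Atp2a2, the calcium pump of the sarcoplasmic reticulum, 11836 ± 1507 CPM. The ATP synthase subunits Atp5b and Atp5a1 reached 10386 ± 870.3 and 7121 ± 305 CPM. Thin filament genes followed, with Tpm1 (tropomyosin) at 9817 ± 588 CPM and Tnnc1 (cardiac troponin C) at 6549.6 ± 365 CPM. The fuel-handling genes Fabp3, which binds fatty acids, and Lpl, which frees them from lipoproteins, reached 8751 ± 191 and 6902 ± 124 CPM. Ckm, the muscle creatine kinase, reached 7678 ± 224 CPM. The other members of the 20 highest were Cox4i1 (8893 ± 181 CPM), Pln (6909 ± 495), Gsn (6230.1 ± 452), Myl3 (5758 ± 53.9), Tcap (5636 ± 443), Ndufa4 (5324 ± 9.34), Uqcrc1 (5168 ± 5.55), Hadhb (5013 ± 459), the haemoglobin gene Hba-a1 (4718 ± 3974) and Aldoa (4586 ± 250.1). These 20 genes held 17.9% ± 0.607 of the reads of annotated genes and the 100 highest held 34.5% ± 0.272. Protein-coding genes took 97.9% ± 0.0492 of the reads, processed pseudogenes 1.09% ± 0.0341 and lincRNAs 0.229% ± 0.00218.

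Of the fixed gene lists, those of energy metabolism and the sarcomere had the highest summed levels. The 18 nuclear genes of oxidative phosphorylation summed to 81357 ± 3819 CPM and the 21 genes of the TCA and glycolysis list to 46342 ± 2313 CPM. The 18 genes of fatty acid uptake and beta-oxidation summed to 35930.2 ± 1627 CPM. The TCA and glycolysis list also holds the creatine kinase genes Ckm (7678 ± 224 CPM) and Ckmt2 (3602 ± 209 CPM), which belong to neither pathway. Its highest members were Ckm and Aldoa. Its member Gapdh had only 6 reads in each library (11.7 ± 3.13 CPM). How well reads of Gapdh were kept or assigned was not measured, so the sum may miss reads of this gene. The 13 protein-coding mitochondrial genes summed to 6589 ± 608 CPM, with mt-Cytb at 2328 ± 116, mt-Co1 at 2172 ± 195 and mt-Nd2 at 491 ± 82.7 CPM. All mitochondrial transcripts together held 0.612% of mouse reads in replicate 1 and 0.701% in replicate 2. How well library making, alignment and filtering kept mitochondrial transcripts was not measured. Their summed level therefore does not rank them against nuclear genes in the heart. The 15 detected genes of the thick and thin filament list summed to 62464 ± 4799 CPM. Z-disc, M-band and costamere genes summed to 20311 ± 528 CPM, with the intermediate filament gene Des at 3141 ± 86.6 CPM and the Z-disc gene Actn2 at 2808 ± 179.7 CPM after Tcap. Calcium handling and excitation genes summed to 24795 ± 1197 CPM, with Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 1747 ± 77.7 CPM. The 18 ribosomal protein genes summed to 4085 ± 397 CPM, led by Rplp0 (713 ± 45.0), Rpl5 (478 ± 90.3) and Rps14 (382 ± 15.1).

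The stress and natriuretic peptide list summed to 5537 ± 31.4 CPM, most of it from Nppa, the atrial natriuretic peptide (2174 ± 40.1 CPM), and the small heat shock gene Cryab (1248 ± 20.2 CPM), followed by Hspb6 (377 ± 19.8 CPM). Clock and clock-output genes summed to 591 ± 24.0 CPM, and the 3 highest were Dbp (162 ± 8.88), Tef (129 ± 11.6) and Nr1d1 (78.1 ± 8.55).

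Markers of the chambers and of cells other than cardiomyocytes were read as well. Ventricular cardiomyocyte genes summed to 16786 ± 856 CPM, led by Pln, Myl3 and the ventricular myosin light chain Myl2 (2935 ± 212 CPM). Atrial cardiomyocyte genes summed to 3589 ± 76.6 CPM, led by Nppa, Myl4 (578 ± 55.4) and Myl7 (374 ± 16.9). Fibroblast markers summed to 7900.4 ± 670.0 CPM, of which Gsn, an actin-severing protein made by many cell types, held most. Dcn (decorin) stood at 504 ± 12.5 CPM and Col3a1 (collagen III) at 364 ± 109 CPM. Smooth muscle and pericyte genes summed to 3734 ± 130.1 CPM, mostly from a gene of cardiomyocytes, Des. The pericyte marker Rgs5 stood at 332 ± 9.82 CPM and Acta2 at 83.0 ± 28.6 CPM. Endothelial markers summed to 1698 ± 116 CPM, led by Fabp4 (432 ± 9.77), Eng (280.0 ± 41.2) and Cav1 (169.6 ± 22.9). Macrophage and other leukocyte markers summed to 599.6 ± 16.4 CPM, led by Cd74 (156 ± 5.63), Lyz2 (155 ± 7.88) and H2-Ab1 (56.9 ± 11.5). Adipocyte markers summed to 117 ± 73.0 CPM, of which Car3 held 88.7 ± 56.4 and Cfd 13.4 ± 5.77, while Ucp1 had 0 reads in replicate 1 and 6 reads in replicate 2. Epicardium and mesothelium markers summed to 67.7 ± 12.7 CPM, led by Upk3b (29.8 ± 2.73), Msln (25.8 ± 9.54) and Upk1b (3.91 ± 1.04). Schwann cell and neuron markers summed to 20.8 ± 0.198 CPM, with Mbp and Dbh at 8.25 ± 1.81 and 4.28 ± 3.81 CPM. Of the 10 markers of thymus and lung, the organs beside the heart, 1 was detected: Lck, with 2 reads in replicate 1 and 0 in replicate 2. Skeletal muscle genes summed to 399 ± 73.0 CPM, of which Acta1, an actin also expressed in the heart, held 370.3 ± 67.9, Myl1 15.6 ± 4.17 and Atp2a1 9.41 ± 0.162.

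Where genes come in sister forms, the form named first held most of the reads in most pairs. Not all pairs set an adult cardiac form against another form. Myl4 and Myl7 stand in the atrial list, Fabp4 stands in the endothelial list, and Nppa and Nppb stand together in the stress list. Shares of such pairs can also reflect chamber and cell content. Myh6 held 99.5% ± 0.0550 of the reads of Myh6 and Myh7, the beta heavy chain of the foetal and stressed mouse heart. Tnni3, the cardiac troponin I, held 100% against Tnni1, the form of the foetal heart and slow muscle, which had 0 of 272 and 0 of 402 reads (lower 95% limits of the Tnni3 share 98.7% and 99.1%). Ryr2 against Ryr1 and Aldoa against Aldoc also reached 100%. Shares above 95% were found for Ckmt2 over Ckmt1 (99.97% ± 0.0476), Atp2a2 over Atp2a1 (99.9% ± 0.0116), Casq2 over Casq1 (99.6% ± 0.267), Actn2 over Actn1 (99.6% ± 0.0840), Nppa over Nppb (98.7% ± 0.595), Ckm over Ckb (98.3% ± 0.0288), Cpt1b over Cpt1a (97.3% ± 1.24), the insulin-responsive glucose transporter gene Slc2a4 over Slc2a1 (97.0% ± 0.603), Cox6a2 over Cox6a1 (95.9% ± 0.835), Eno3 over Eno1 (95.3% ± 0.719) and Fabp3 over Fabp4 (95.3% ± 0.199). Slc25a4 held 92.9% ± 0.133 against Slc25a5, Myl3 90.9% ± 0.717 against Myl4 and Myl2 88.7% ± 1.18 against Myl7. Pgam2 held 86.1% ± 1.02 against Pgam1 and Actc1 85.3% ± 3.41 against Acta1. Tnnt2 held 90.7% ± 5.15 against Tnnt1, on 148 and 267 reads of Tnnt2 and 22 and 16 of Tnnt1. Tnnt2 stood at only 384 ± 56.5 CPM, against 6549.6 ± 365 CPM for Tnnc1. How fully Tnnt2 transcripts were recovered was not measured, so the share of Tnnt1 in the heart stays uncertain.

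Mixed pairs were found mainly among genes of energy metabolism. Cox7a1, the heart and muscle form of a cytochrome oxidase subunit, held 50.3% ± 2.52 against the liver form Cox7a2, and Cox8b held 78.9% ± 1.39 against Cox8a. The lactate dehydrogenase genes Ldhb and Ldha were split 58.4% ± 0.830 to the heart form Ldhb. The muscle phosphofructokinase Pfkm held 63.3% ± 2.07 against the liver form Pfkl. Hk1 held 33.5% ± 5.16 against Hk2, the insulin-responsive hexokinase. The Cox7a1 share was 52.0% in replicate 1 and 48.5% in replicate 2. When reads of known transcripts alone were counted, the mean share was 56.0% for Hk1, so that the leading form changed, and 45.7% for Cox7a1.

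The 2 replicates differed by little in most genes and by a factor of 3 to 4 in haemoglobin genes. Hba-a1 was 3.95-fold higher in replicate 1 (95% counting interval 3.69 to 4.22, 3239 against 1202 reads), Hba-a2 3.78-fold, Hbb-bt 3.54-fold and Hbb-bs 3.48-fold. Alas2, the enzyme that starts haem synthesis in red cell precursors, was 3.40-fold higher (2.25 to 5.25, 79 against 34 reads; exact binomial test, adjusted p = 2.10e-07). Adjusted p was 5.40e-107 for Hba-a2, 3.27e-169 for Hbb-bs and 1.59e-22 for Hbb-bt in the same exact test. Hba-a1 and Hba-a2 lie at chr11:32283511-32284465 and chr11:32296489-32297298, and their near-identical sequences make the split of reads between them uncertain, as for Hbb-bs and Hbb-bt. Bpgm, another erythroid marker, had 26 and 31 reads, and Slc4a1 had 0 reads in both libraries. Hbb-bt, Alas2, Bpgm and Slc4a1 lie outside the fixed rule and were chosen after their values were seen. The summed erythroid list stood at 8791 ± 7178 CPM.

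Across genes, levels in the replicates correlated with Pearson's r = 0.931 and Spearman's rho = 0.911 over 8098 genes, which are not independent replicates. Of 1757 genes with at least 100 reads, 96.2% lay within 1.5-fold and the median absolute log2 ratio was 0.16. The coefficient of variation beyond counting error was 6.66% (bootstrap 95% interval 5.70 to 7.54). An unadjusted exact p under 0.05 was found for 579 genes (7.15%) and an adjusted p under 0.05 for 56, of which 26 differed at least 2-fold and were called: 5 from the erythroid list and 21 outside it. Replicate 1 was the higher in 18 of the 26 and replicate 2 in 8. With reads of known transcripts alone, 15 genes were called, 3 of them higher in replicate 2, and without genomic models 38 were called, 29 of them higher in replicate 1. At least 1 read was found in both libraries for 11492 of 14534 genes, 1208 genes were read in replicate 1 alone and 1834 in replicate 2 alone. Of the genes read in a single library, 6 had 10 or more reads there.

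**Figure D1:**
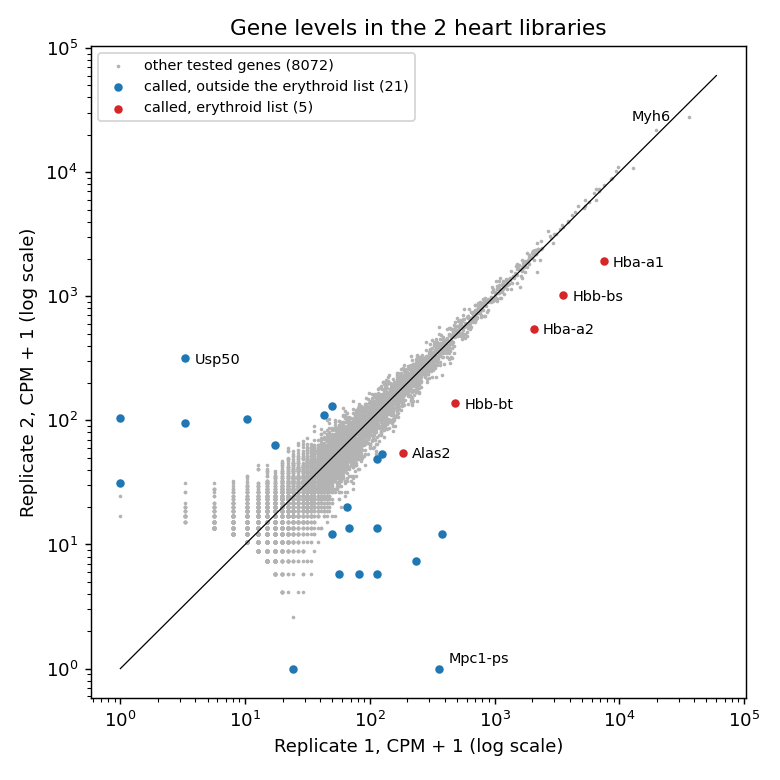
Gene levels in the 2 heart libraries, as CPM + 1 on log axes, with replicate 1 on the x axis and replicate 2 on the y axis and a line at equal levels. Grey points are tested genes that were not called; red points are the 5 called erythroid genes, all below the line, and blue points the 21 called genes outside that list.

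Outside the erythroid list, 16 of the 21 called genes overlapped or adjoined other models with reads on the same strand, and several were pseudogenes. The pseudogene Mpc1-ps (chr12:110858565-110858894) had 155 reads in replicate 1 and 0 in replicate 2, at least 75.6-fold higher against 3 reads, the limit that a count of 0 allows (exact lower 95% limit of the ratio 60.8). Gm10774 (chr2:126709354-126709557) was 37.0-fold higher (101 against 4 reads), Gm29216 (chr1:24615706-24616197) 33.9-fold (162 against 7), Gm28035 23.9-fold (interval 7.72 to 120, 49 against 3), Gm45837 17.1-fold (5.38 to 86.8, 35 against 3) and Oaz1-ps 8.97-fold (49 against 8). Hgs carries a pair of gene identifiers at the same place on chr11. ENSMUSG00000025793.16 was 11.7-fold higher in replicate 1 (3.56 to 60.8, 24 against 3 reads), and ENSMUSG00000116045.1 was 3.81-fold higher in replicate 2 (39 against 7 reads). Mir7219 had 10 reads in replicate 1 and 0 in replicate 2, at least 4.88-fold against 3 reads (exact lower limit 3.28). Retreg2 was 5.31-fold higher in replicate 1 (29 against 8) and Wdfy1 4.39-fold (21 against 7).

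In the other direction, Usp50 (chr2:126709096-126783470) had 1 read in replicate 1 and 199 in replicate 2, a ratio of 136 (24.1 to 5395). Phyhd1 had 1 and 59 reads, a ratio of 40.3 (6.96 to 1618). AC154200.1 had 0 and 65 reads, at least 14.8-fold higher in replicate 2 against 3 reads (exact lower limit 11.7), and Apbb3 0 and 19 reads, at least 4.33-fold (3.19). The fat-cell carbonic anhydrase Car3 was 2.63-fold higher in replicate 2 (81 against 21 reads; exact test, adjusted p = 0.00605) and Tmem204 2.62-fold (69 against 18). For 15 of the 21 called genes outside the erythroid list, the difference fell under 2-fold once reads of same-strand models that overlap or adjoin the gene were added, a step chosen after the values were seen.

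Among the fixed lists, the erythroid list differed most between the replicates, and the medians of all other lists lay between -0.24 and 0.38 on the log2 scale. Directions are relative to the nuclear total: scaling by ERCC reads would move every log2 ratio by -0.27, and the other scalings tried moved it by -0.04 and -0.03. All 6 erythroid members with at least 10 reads were higher in replicate 1, with a median log2 ratio of 1.81, at percentile 100 of 10000 random lists of matched level (95% of these between -0.23 and 0.19). The exact test was passed by 5 members over all genes and by 5 adjusted over the list alone. Mitochondrially encoded genes had a median of -0.24, at percentile 0.480, with 8 of 10 members lower in replicate 1. None of them passed over all genes and 4 did adjusted over the list alone. Ribosomal protein genes had a median of -0.19, at percentile 0.670, with 16 of 18 members lower in replicate 1. Rpl4 (-0.59, adjusted p = 0.0266 in the exact test) was the only member to pass over all genes, and 2 passed adjusted over the list alone. Calcium handling genes had a median of 0.13, at percentile 97.8, with 12 of 16 members higher in replicate 1. Atp2a2 (0.26) and Pln (-0.15) passed over all genes in opposite directions, and 4 members passed adjusted over the list alone. With log2 ratios taken relative to the median of genes of the same transcript length class, a step chosen after seeing the data, the ribosomal and calcium lists stood at percentiles 9.01 and 94.0.

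The remaining lists lay inside the central 95% of random lists at the minimum of 10 reads. With a minimum of 50 reads, the fibroblast list (0.25, percentile 99.5) and the smooth muscle and pericyte list (-0.38, percentile 1.11) lay outside it. The smooth muscle and pericyte list then held only Kcnj8 (-0.80), Acta2 (-0.70), Des (-0.06) and Rgs5 (0.06), none of which passed over all genes. Kcnj8 lies outside the fixed rule and was named after its value was seen. At 10 reads, the fibroblast list was near the edge, with a median of 0.20 at percentile 97.0. Its members Col3a1 (0.62, exact test, adjusted p = 0.00891) and Gsn (0.15) passed over all genes and 3 passed adjusted over the list alone. The thick and thin filament list had a median of -0.02, though Myh6 was higher in replicate 1 (0.40, exact binomial test, adjusted p = 1.31e-135) and Tpm1 lower (-0.12). Only these 2 members passed over all genes, and 6 passed adjusted over the list alone. The Z-disc list had a median of -0.04, with Tcap (-0.16) passing over all genes and 1 member adjusted over the list alone. Fatty acid genes had a median of -0.09, with 15 of 18 members lower in replicate 1. Acaa2 (-0.28) and Hadhb (-0.19) passed over all genes, and 3 members passed adjusted over the list alone. Nuclear oxidative phosphorylation genes had a median of -0.07, with 3 members past the test over all genes, of which Uqcrc2 (-0.37) differed most, and 5 adjusted over the list alone. The TCA and glycolysis list had a median of -0.10, with 4 members past the test over all genes and 8 adjusted over the list alone. The kinase Pdk4, which holds back pyruvate oxidation, differed most among these 4, at 0.62 in the opposite direction. Ventricular genes had a median of -0.15, with Pln passing over all genes and 2 members adjusted over the list alone.

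No member of the endothelial (median 0.10), skeletal muscle (0.38), leukocyte (-0.17), smooth muscle and pericyte (-0.03), clock (-0.08), stress (0.00) or atrial (0.00) lists passed over all genes. Adjusted over the list alone, 2 endothelial members and 1 skeletal muscle member passed, and 0 of the other 5 lists. The adipocyte, epicardium, Schwann cell and thymus and lung lists had fewer than 3 members with 10 reads, so no median was calculated. Of their members, Car3 was the only gene to pass, over all genes and adjusted over the list alone.

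**Figure D2:**
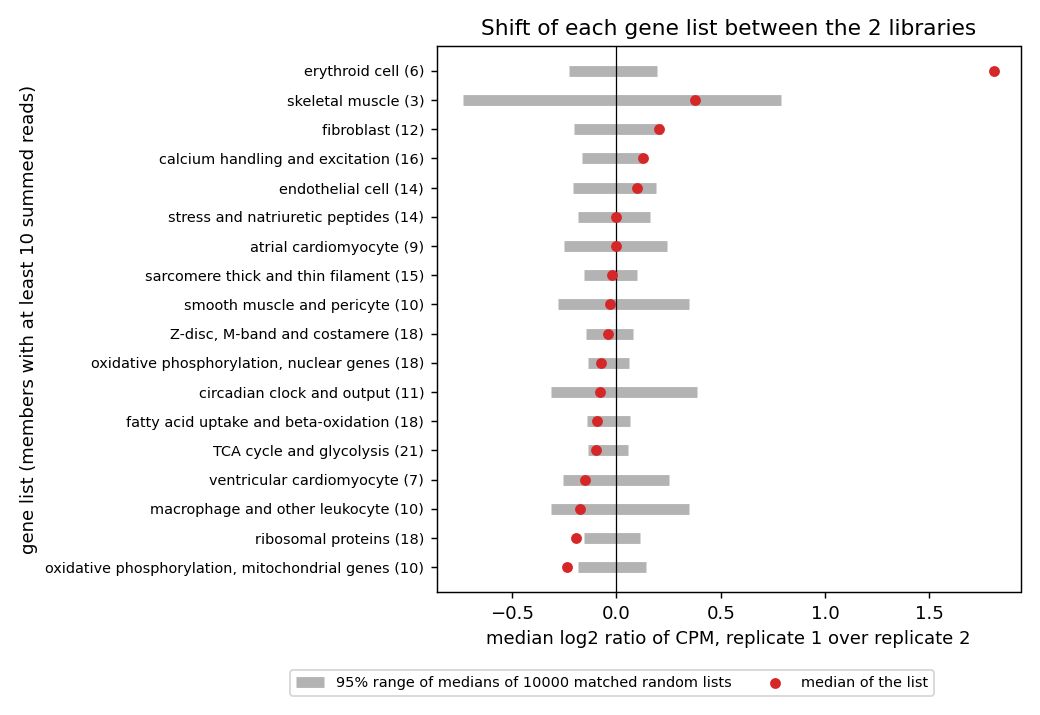
Median log2 ratio of CPM, replicate 1 over replicate 2, for each fixed gene list with at least 3 members of 10 or more summed reads (red points, number of members in parentheses), with the central 95% of the medians of 10000 random lists matched on level (grey bars). The erythroid list lies at 1.81, far to the right of its grey bar, and the mitochondrially encoded list at -0.24 and the ribosomal list at -0.19 lie to the left of theirs.

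Of 550 genes tested for isoform use, 1 passed the test between the replicates. Rsrp1 (chr4:134923592-134927671), which encodes an arginine- and serine-rich protein, used the transcript Rsrp1-201 for 35.6% of 59 known-transcript reads in replicate 1 and for 72.7% of 88 reads in replicate 2. The change was -37.1 percentage points (Fisher's exact test, adjusted p = 0.00509). The other reads came from Rsrp1-204, which retains 1302 bases at chr4:134925433-134926734, an internal part of exon 3 that is not coding. An unadjusted p under 0.05 was found for 26 genes, 4.73% of those tested. Recovery of simulated changes was measured for genes with at least 50 reads in each library, and was not measured for genes nearer the minimum of 20 reads.

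Among known-transcript reads, the fixed isoform genes mostly used a single transcript, and the isoform shares that follow are shares of these reads. ISM reads are left out of them. Over all genes, ISM models made up 20.0% of known and ISM reads at 4000 bases or more, against 8.27% under 1000 bases. These shares can therefore favour short transcripts. The main transcript was shorter than the second in Ldb3, Lmna, Asph and Trdn, among others, but longer in genes such as Vegfa and Eif4a2. Of 70 genes, 27 had at least 50 known-transcript reads in each library. Their main transcript held a median of 95.9% of these reads, and at least 90% in 16 genes. None of the 20 fixed genes tested passed the test between the replicates, and the median difference between replicates was 0.746 percentage points. The largest was 18.7 points in Trdn.

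Isoforms were mixed most evenly in 4 genes, in which the main transcript held less than 50% of the known-transcript reads in the mean of the replicates. Gnas, the stimulatory G protein alpha subunit, used Gnas-207 for 40.3% ± 0.412 and Gnas-208, which adds a coding exon of 45 bases at chr2:174336747-174336791, for 35.5% ± 1.79. Trdn (triadin, an anchor of calsequestrin in the sarcoplasmic reticulum) was split between the single-exon transcript Trdn-204 (48.4% ± 13.2) and the 8-exon Trdn-208 (43.7% ± 8.91). Trdn-204, at chr10:33198705-33200369, has no coding bases and lies past the last exon of Trdn-208, with which it shares no exon. The split in Trdn is therefore not one between forms of the protein. Vegfa used Vegfa-202 for 48.8% ± 4.16 and Vegfa-207, which adds a coding exon of 72 bases at chr17:46022277-46022348, for 43.0% ± 5.39. In both Trdn and Vegfa the leading transcript differed between the replicates. Trdn-204 held 57.7% in replicate 1 and 39.1% in replicate 2, against 37.4% and 50% for Trdn-208. Vegfa-202 held 45.9% and 51.7%, against 46.8% and 39.2% for Vegfa-207. Neither gene passed the test.

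Among genes with a clear main transcript, Lmna used Lmna-203, the transcript with 10 exons, for 62.9% ± 2.20 and the 12-exon Lmna-201 for 36.7% ± 2.79. Ndrg2-201, with a coding exon of 42 bases at chr14:51911086-51911127, held 64.9% ± 1.36 of Ndrg2. Myl6-201 held 66.0% ± 4.07 of Myl6, against 25.9% ± 8.82 for Myl6-206, which adds an exon of 45 bases. Eif4a2-201 held 75.4% ± 3.13 and Asph-206, with 5 exons, 76.2% ± 4.17. Myh6-201 held 75.5% ± 0.873 of the known-transcript reads of Myh6 and Myh6-205, which lacks 64 non-coding bases of exon 2 at chr14:54965836-54965899, held 23.7% ± 0.830. Ldb3-203, with 8 exons and 1586 bases, held 84.4% ± 8.69 of the known-transcript reads of Ldb3, a Z-disc gene. Ldb3-201, with 14 exons and 5119 bases, held 8.33% ± 6.42. The M-band gene Myom1 used Myom1-203, without the coding exon of 294 bases at chr17:71082203-71082496, for 94.2% ± 0.745. In the mutually exclusive exon pair of Pkm, Pkm-202 with the exon at chr9:59675029-59675195 held 95.6% ± 0.0446. Slc25a3-206, with the exon of 125 bases at chr10:91122207-91122331 in place of the alternative of 122 bases, held 96.3% ± 0.527. Rbm24-201 held 95.9% ± 2.79. Over reads of all classes, the main share was 25.4% in Trdn, 37.5% in Myh6, 37.8% in Myom1, 38.5% in Ndrg2, 43.8% in Ldb3 and 49.4% in Asph.

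Known transcripts held most of the reads of these hearts, and partial or unannotated models of annotated genes most of the remainder. Known transcripts received 73.4% ± 0.0810 of mouse reads, ISM models 10.5% ± 0.207, NIC models 5.0% ± 0.307, NNC models 3.5% ± 0.120, genomic models 4.51% ± 0.328, antisense loci 2.58% ± 0.190 and intergenic loci 0.488% ± 0.000228. With at least 5 reads per model, the shares of NNC models, antisense loci and intergenic loci were 1.37%, 1.40% and 0.216%. Of ISM reads, 72.2% ± 0.188 matched the 3' part of a transcript and 3.80% ± 0.0940 the 5' part. Models with a single read made up 62.4% of mouse models in replicate 1 and 61.5% in replicate 2.

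Some heart genes were read mainly as models that GENCODE M21 lacks. The 10 most read of these, found in both libraries, included models of Myh6, Oaz1, Srl, Atp2a2, Idh3b, Tmed2, Mpc1 and Vdac3. A pair of NIC models of Myh6 at 4570.4 ± 1142 and 1447 ± 215 CPM held 14.2% ± 0.801 and 4.53% ± 0.214 of its reads of all classes. Both ended the intron at chr14:54942005-54942352 3 bases away from the end at 54942002 used by Myh6-201 and Myh6-205. In Srl (sarcalumenin, a calcium-binding protein of the sarcoplasmic reticulum), a model with the intron chr16:4493881-4522992 in place of chr16:4493878-4522992 held 68.7% ± 2.51. Oaz1, the ornithine decarboxylase antizyme whose translation shifts frame, had 95.4% ± 0.474 of its reads in a model without the annotated intron of 4 bases at chr10:80828292-80828295. Mpc1, a subunit of the mitochondrial pyruvate carrier, had 95.9% ± 0.177 in a 4-exon model with an unannotated intron at chr17:8283962-8296534. Vdac3, a channel of the outer mitochondrial membrane, had 86.6% ± 3.04 in a model with the intron chr8:22583737-22587548. The end of this intron is unannotated and lies 1 base from an annotated end at 22587549. Tmed2 had 85.5% ± 4.34 in a 5-exon model. Idh3b, a subunit of the NAD-dependent isocitrate dehydrogenase, had 82.0% ± 1.84 in a model with an intron of 825 bases at chr2:130279438-130280262, where Idh3b-201 has one of 536 bases. In Atp2a2, 6.24% ± 0.320 of reads had a single intron at chr5:122500814-122501563 in place of a pair of annotated introns. Its end at 122501563 is unannotated and lies 4 bases from the annotated end at 122501567. Because splice-site sequences were not examined, whether such unannotated ends are real splice sites was not settled.

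The more reads a model had, the more often its intron chain was also read in the other replicate. Of NIC models, 38.2% ± 4.74 were shared, and of NNC models 20.9% ± 4.22. When each junction was matched within 10 bases, the shares were 45.6% and 46.4%. With exact matching, models with a single read were shared at 23.0% ± 5.34 and 12.9% ± 4.12, and those with at least 10 reads at 99.9% ± 0.190 and 100%. A total of 4956 NIC and NNC chains of 2783 genes were read in both libraries, and 657 of them had at least 5 reads in each.

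**Figure D3:**
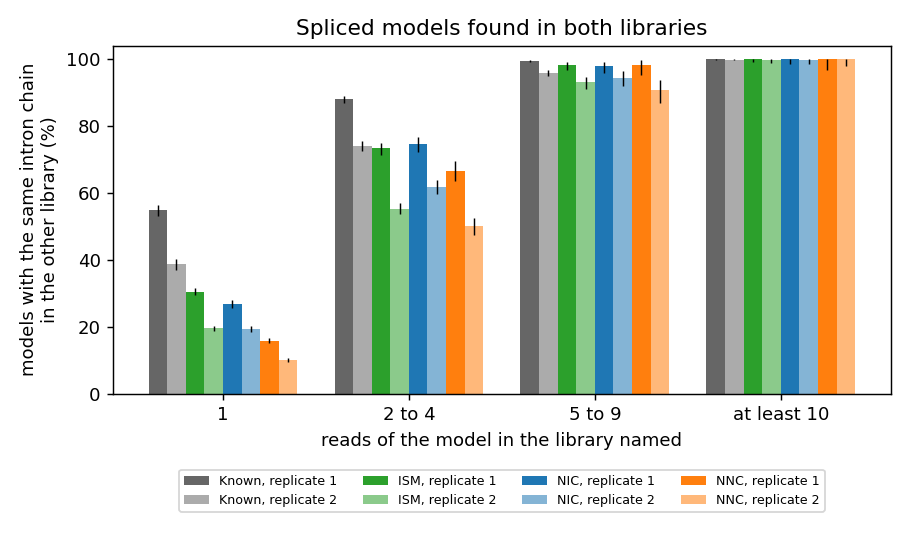
Share of spliced models whose exact intron chain was also read in the other library (percent, bars from 0), by the number of reads of the model, for known, ISM, NIC and NNC models of each library, with exact 95% intervals. With at least 10 reads, nearly all models of every class were shared, against 23.0% ± 5.34 of NIC and 12.9% ± 4.12 of NNC models with a single read.

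The longest heart genes were not read in full. Ttn (titin, longest annotated transcript 106824 bases) had 55 and 105 reads, none from a known transcript, which allows known shares of up to 5.45% and 2.86%, and its longest model measured 13927 bases. Ryr2, the calcium release channel (16814 bases), had 50 and 80 reads, none from a known transcript (up to 6% and 3.75%), and a longest model of 6575 bases. Over all genes, ISM models made up 8.27% ± 0.598 of known and ISM reads for transcripts under 1000 bases, 13.3% ± 0.381 from 1000 to under 2000 bases, 8.68% ± 0.274 from 2000 to under 3000, 11.1% ± 0.536 from 3000 to under 4000 and 20.0% ± 0.671 at 4000 bases or more. ISM models held 74.5% and 67.6% of Ttn reads and 64% and 46.2% of Ryr2 reads.

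ERCC spike-in RNAs, which do not come from the mouse, were measured beside the mouse genes. The levels of 43 ERCC RNAs, single-exon molecules of 274 to 1994 bases, correlated between the replicates with Pearson's r = 0.967 and Spearman's rho = 0.893 across RNAs. The coefficient of variation beyond counting error was 2.05% over the 10 ERCC RNAs with at least 100 reads, against 6.66% for mouse genes, a difference that was not tested. None of the 14140 ERCC reads fell in an unannotated model, which allows a share of up to 0.0212%. Because these RNAs have a single exon, this share does not measure error in spliced models such as NIC and NNC. Nuclear mouse reads per ERCC read were 67.4 in replicate 1 and 81.2 in replicate 2.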

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

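No test was run on the loci named here, and they were chosen after their values were seen. Reads outside annotated genes did not enter the comparisons of genes and stand here because spliced loci among them were read in both replicates above the limit that a count of 0 allows. With the same intron chain in each library, 44 spliced chains of intergenic loci and 87 spliced chains of antisense loci were read in both replicates. The most read intergenic locus lay at chr11:31545795-31549649 on the plus strand, with 188 reads in replicate 1 and 278 in replicate 2. Its intron at chr11:31546002-31548000 was carried by 184 and 272 of these reads, or 428 and 432 CPM. A chain of 5 introns on chr8 between 77968171 and 77985191, on the minus strand, had 24 and 31 reads, and a chain with 1 intron on chrY, at 43919008-43919084, had 31 and 25 reads.

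Models with a single exon held 96.0% of the reads of antisense loci in each replicate. The most read antisense locus began at chr17:39843013 on the minus strand, with 1005 reads in replicate 1 and 1104 in replicate 2. It lay opposite Gm26917 in both and also opposite Gm42418 in replicate 1. What kind of RNA its reads come from was not examined. A locus opposite Klhl31 had 207 and 333 reads. The most read spliced antisense chain, on chr5 with an intron at 148512003-148551952 on the plus strand, had 13 and 27 reads. How strand was assigned to these reads was not given in the sources used here.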

How the results depend on the processing

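The tests with adjoining models pooled, without the erythroid list, relative to transcript length classes and on ERCC reads were chosen only after the result was seen; the other alternatives were planned. Among the values that answer a comparison, 66 stayed on the same side of their threshold or within the spread, 37 moved and 2 weakened; the cause was not tested unless given here. Among the other values 109 stayed, 10 called genes weakened and 5 changed sign when pooled, and 13 isogene shares moved with known transcripts alone. When 50 reads were required, 2 lists left the central 95% of random lists: fibroblast (0.25) and smooth muscle and pericyte (-0.38). Both counts of values that stayed include values that could not move. These are each replicate alone, and list percentiles under median-of-ratios scaling, which shifts all genes by the same amount.

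Class shares depended most on rare models. With at least 5 reads per model, known transcripts held 81.7%, ISM 8.18%, NIC 3.5%, NNC 1.37%, genomic 3.61%, antisense 1.40% and intergenic 0.216%. With spike-in RNAs kept, known transcripts held 73.8% and intergenic loci 0.482%, and without mitochondrial genes 73.2% and 0.491%. With at least 5 reads in each library, 7330 genes were detected in both. Pearson's r was 0.897 with no read minimum, 0.947 with at least 100 summed reads, and 0.920 and 0.956 with pseudocounts of 0.1 and 10 CPM. Spearman's rho was 0.925 with at least 100 reads and 0.906 with known transcripts alone.

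Called genes numbered 15 with known transcripts alone (3 higher in replicate 2), 56 with no fold minimum (28 in each direction) and 11 after pooling adjoining models (9 and 2). Pooling turned the log2 ratio of Mpc1-ps from 8.83 to -0.21, Gm10774 from 5.05 to -0.45, Oaz1-ps from 3.09 to -0.0204, Phyhd1 from -4.76 to 0.26 and the Hgs model ENSMUSG00000116045.1 from -1.85 to 0.12, all inside the 2-fold limit. Without genomic models 38 were called and 29 were higher in replicate 1. Other scalings left the number within 1.5 times. Without the erythroid list 20 were called. Relative to the median of their length class, the calcium list (0.10) and the ribosomal list (-0.10) no longer stood outside the central 95%. Myh6 held 99.4% against Myh7 with known transcripts alone, and the median main isoform share was 71.8% over all classes. With junctions matched within 10 bases, 45.6% of NIC and 46.4% of NNC models were shared, and with at least 5 reads 97.9% and 96.7%. Over all reads, ISM models held 12.2%, 7.51%, 9.43% and 15.4% from 1000 bases upward. The alternative for SIRV reads was not run. ERCC reads were used in their place, but single-exon RNAs cannot measure error in spliced models. Each replicate alone lies within 1 SD of the mean of 2 by construction, which says nothing about stability. No paired analysis was possible because the series holds 1 group. Depth limits most what can be said of genes under 10 reads and of single-read models, which made up 62.4% and 61.5% of mouse models.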

Other observations

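The tests of red cell RNA, scaling and transcript length for the erythroid genes and both tests of adjoining models were chosen only after the result was seen; the other 3 tests were written before their values were known, but after the trend itself had been noticed.

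Besides the genes named by the fixed rule, smaller differences between the replicates fell on several enzymes of the mitochondrial matrix, chosen here after their values were seen. Idh2 (log2 ratio -0.30, exact binomial test, adjusted p = 3.10e-06), Mdh2 (-0.30, adjusted p = 0.00123), Suclg1 (-0.67, adjusted p = 0.000324) and Sucla2 (-0.34, adjusted p = 0.00605) were lower in replicate 1, all in the same exact test. Higher in replicate 1 were Hspa5, the chaperone of the endoplasmic reticulum (0.48, exact test, adjusted p = 2.51e-10) and Gpc1, a cell-surface proteoglycan (0.43, adjusted p = 6.05e-06). Each compares 1 library with another and covers counting error only.

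The erythroid genes were higher in replicate 1. For a difference in depth or scaling, Hba-a1 was predicted to fall under a log2 ratio of 1 in at least 1 of 4 scalings. Its lowest value was 1.71, with ERCC reads. Each scaling moves all genes by the same amount, by -0.27 at the most here. From 1.98 with nuclear totals, none of the 4 could reach 1, so this outcome decides nothing beyond the difference being larger than these shifts. Short transcripts as a class were not higher: 91 other genes with main transcripts of 554 to 703 bases, the range of the globins, had a median of -0.073. The 5 abundant erythroid genes lay within 0.23 of each other on the log2 scale, which is consistent with more RNA from red blood cells left in the tissue of replicate 1, as a hypothesis. Among members chosen after their values were seen, Slc4a1 was not read and the log2 ratio of Bpgm was 0.30 with a counting SE of 0.38; no biological explanation was tested because the series holds 1 group.

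Large differences of single genes outside the erythroid list often had a mirror image next door. After adding the reads of same-strand models that overlap or adjoin each gene, 15 of the 21 fell under 2-fold. Dilution by neighbours that do not differ would give few neighbours that differ the opposite way. Yet for 13 of the 16 genes with neighbouring reads they did (exact binomial p under 0.05, not adjusted), at 9 places. At 4 of these places both partners were called: Usp50 and Gm10774, AC154200.1 and Oaz1-ps, Phyhd1 and Gm28035, and the pair of Hgs identifiers. Such pairs count from both sides and were selected as differing, so no number by chance is given. These differences may therefore come from reads of the same place being assigned to different models in each library; 5 genes, among them Car3, Tmem204, Wdfy1 and Hsph1 (the last chosen after its value was seen), had no such neighbour and stay open, as do Retreg2, Apbb3 and Mir7219, whose neighbours did not differ the opposite way.

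Long transcripts were slightly higher in replicate 1, with median log2 ratios of -0.06, -0.11, -0.05, 0.09 and 0.09 from under 1000 to at least 4000 bases. Whether abundant genes account for it was not decided, because a rank correlation of 3248 genes could not fall under 0.1 without 100 of them: Spearman's rho was 0.223, 0.222 without the 100 most abundant, and still 0.162 without the 100 that carry most of it. If long cDNA had been recovered better, long transcripts should also be higher within a gene, but the median within-gene difference of 29 genes was 0.11 with a standard error of 0.160, which decides nothing. A slope over 767 known transcripts of 358 genes, added after that outcome, was -0.00355 ± 0.0321 (SE) per doubling of length, against 0.0632 ± 0.00616 between genes, which speaks against such recovery as the whole cause by a narrow margin. Reads of known transcripts were assigned by model and not by read length, so partial copies could hide a within-gene trend, and no biological explanation was tested.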
